A study of Mus musculus with 10 samples.

How the data were processed

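Expression was measured in diploid AB1 mouse ES cells, a male line (WT, passages 18 and 20), and in ES cell lines trisomic for chromosome 6 (Ts6, passages 9 and 18), 8 (Ts8, passages 10 and 13), 11 (Ts11, passages 8 and 11) or 15 (Ts15, passages 11 and 14), with 2 biological replicates per group and 10 arrays in all. Per the labels' protocols, the cells were grown on irradiated fibroblast feeder cells that were depleted by settling before RNA extraction, and the RNA was amplified and labelled with Cy3. Per the file headers, the arrays were 1-colour Agilent mouse arrays with probes for messenger RNAs and lincRNAs placed on mm9, and the deposited intensity values were made with Agilent Feature Extraction 10.7.3.1, with spatial and multiplicative detrending on, background correction off and surrogate values for dim spots. No normalization between arrays is recorded for these intensities. The deposited series table held log2 values: set against the scanner's log2 values they increased with signal, with a correlation across probes of 0.998 to 1.000. All of its columns had the same SD of 3.81, as after quantile normalization, and medians of -3.4043 and -3.4043 (WT replicates 1 and 2), -3.4169 and -3.4178 (Ts6), -3.3714 and -3.3679 (Ts8), -3.3249 and -3.3211 (Ts11), and -3.3783 and -3.3785 (Ts15). Why the medians differ between groups while the SD is the same is not recorded, so the table served only as an alternative.

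Each array had 62976 spots, 59305 of them noncontrol, and no spot was saturated. The share of noncontrol spots well above background was 77.9% and 78.5% in WT, 71.6% and 71.5% in Ts6, 80.2% and 74.9% in Ts8, 77.0% and 71.4% in Ts11, and 72.3% and 73.3% in Ts15. The file of Ts15 replicate 2 had been saved through a spreadsheet, with values in 3 significant digits and 58 changed gene names, so names came from the other arrays. The array barcodes in the headers placed WT, Ts6, Ts8 and Ts11 on slide 1 and both Ts15 arrays on slide 2. On slide 1 these groups filled slide columns 1, 2, 3 and 4 in that order, so group and slide column cannot be told apart. In every group replicate 1 was in slide row 1 and replicate 2 in slide row 2.

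Values were log2 of the processed signal minus the 75th percentile of the array, averaged over replicate spots. Of 55681 probes, 176 with a flagged value on some array were left out, as were probes not well above background on both arrays of at least 1 group, which left 43056. Names were updated by RefSeq accession where the reference table held it (26762 of 28390 probes with an accession, 2878 names changed); positions are those of the mm9 probes in the files. The probe with the highest mean over all arrays stood for its gene, chosen without use of the groups, which gave 28193 genes. Of the 691, 282, 664 and 546 called genes that had several probes in Ts6, Ts8, Ts11 and Ts15, 16.8%, 15.6%, 18.5% and 26.2% had a probe of the opposite direction.

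Groups were compared with limma 3.58.1 in R 4.3.3: 1 mean per group, moderated variances with 5 residual and 2.64 prior degrees of freedom, and Benjamini-Hochberg adjustment within each comparison, with an adjusted p under 0.05 as a call. Each trisomic line, and the mean of the 4 lines, was compared with WT, and the 6 pairs of lines with each other; all tests were two-sided. The dosage shift of a chromosome was the mean log2 difference from the WT mean of its genes minus that of the 15 autosomes trisomic in no line, tested by an exact permutation test of 2 arrays against 8. A fold against a group with no array above background is given as a bound against the lowest signal called well above background. Figures and tables were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.

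The comparisons, tests, alternatives, 29 gene lists and the rule for named genes were fixed before the data were examined. The lists cover naive pluripotency, primed epiblast, endoderm, mesoderm, neuroectoderm, trophectoderm, the 2-cell-like state, germline genes, feeder cells, p53 targets, proteasome, heat shock, the unfolded protein and amino acid response, cytosolic ribosome, DNA replication, mitosis, lysosome, interferon response, glycolysis and hypoxia, oxidative phosphorylation, cholesterol synthesis, imprinted genes, Y-linked genes, targets of ERK, Wnt, LIF and Stat3, and Myc, cell adhesion and matrix, and tumour suppressors and oncogenes. Of 840 members, 826 were found on the array. Lists with at least 5 members were tested with camera (preset correlation 0.01), leaving out members on the trisomic chromosome, with adjustment over the 29 lists; camera with an estimated correlation and fry were alternatives. Named genes were, per line, the 5 highest and 5 lowest called genes outside the trisomic chromosome and the 5 highest on it (with a symbol that is no predicted or clone name, above background on at least 1 array of each group, and with every array of the line beyond every WT array), the 3 highest and 3 lowest bounds, the 2 to 4 members with the smallest adjusted p of each list that was called or had at least 3 called members, and Pou5f1, Sox2, Nanog, Zfp42, Klf4, Trp53, Cdkn1a, Myc and Eif2s3y. For the mean of the lines the 8 highest and 8 lowest of such genes were taken, and for pairs the 2 highest and 2 lowest; transcripts without a gene symbol that the rule took are left unnamed.

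The procedure was tested on simulated data with known changes, 4 simulated lines against WT: 9.19% of 283 genes changed by log2(3/2), 48.7% of 261 changed by 1 and 86.7% of 256 changed by 2 on the log2 scale were called in the right direction. Of 26512, 26470, 25972 and 26863 unchanged genes, 8, 2, 6 and 5 were called, which were 7.2%, 2.3%, 5.6% and 5.2% of all calls. The simulated noise was independent between genes and arrays. Effects of slide, slide column or passage were not in it, so it does not give the rate of false calls in the real arrays. Alternatives were other background corrections, normalizations, filters, probe summaries, variance models and array weights, passage as a covariate, replicate number as a block, and leaving out each array in turn. Replicate numbers are not treated as pairs, since the labels give them no meaning across groups, although they matched the slide row of the array. The same-number correlation between groups was 0.39 for Ts8 and Ts11 and 0.21 for Ts6 and Ts15. In the other pairs of groups it lay between -0.10 and 0.08.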

Results

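Gene expression was measured in diploid mouse embryonic stem (ES) cells of the male line AB1 and in 4 ES cell lines that carry 3 copies of 1 autosome instead of 2. The lines, called Ts6, Ts8, Ts11 and Ts15, are trisomic for chromosome 6, 8, 11 or 15, and the AB1 cells (WT) were the control. The labels name the strain of the 4 lines as 129 S7/SvEvBrd and give neither their sex nor a parent line, so a difference from WT can include a difference of origin. WT was taken at passages 18 and 20 and the lines at passages 8 to 14, apart from Ts6 replicate 2 at passage 18. A difference from WT can thus also include a difference of passage. RNA of 2 biological replicates per group, taken at different passages, was hybridised to 10 1-colour arrays that carry probes for messenger RNAs and for long intergenic noncoding RNAs (lincRNAs). Between 71.4% and 80.2% of the noncontrol spots of an array were well above background, and 28193 genes, 4146 of them lincRNAs, were tested. The correlation across genes between the 2 arrays of a group ranged from 0.992 to 0.996 (genes are not independent replicates), which mostly reflects differences of level between genes. With values centred per gene it was 0.39 in WT, 0.74 in Ts6, 0.48 in Ts8, 0.44 in Ts11 and 0.62 in Ts15. The number of arrays limits the precision of every value. Both Ts15 arrays were on slide 2 and the other 8 arrays on slide 1, so a difference of Ts15 from another group that is not tied to chromosome 15 cannot be told apart from a difference between slides. On slide 1 each group filled its own column of arrays. A difference between these groups that is not tied to a trisomic chromosome cannot be told apart from a difference between slide columns.

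How far expression of a whole chromosome follows its copy number was asked first. In each line the genes of the trisomic chromosome were higher than in diploid cells, by much less than the log2(3/2) of 0.58 that 3 copies against 2 would give if transcript followed gene number. Relative to the 15 autosomes trisomic in no line, the 1456 genes of chromosome 6 were shifted by 0.20 ± 0.003 on the log2 scale in Ts6 (mean ± SD, n = 2 arrays), a 1.15-fold increase. The shift was 0.26 ± 0.006 for the 1498 genes of chromosome 8 in Ts8, 0.22 ± 0.01 for the 1996 genes of chromosome 11 in Ts11, and 0.22 ± 0.01 for the 1105 genes of chromosome 15 in Ts15. These shifts were 33.96%, 43.7%, 37.1% and 37.3% of log2(3/2). In 8 of 8 arrays the trisomic chromosome had the highest shift of the 19 autosomes, and the autosomes trisomic in no line lay between -0.05 and 0.08. The shift was spread over many genes. In Ts6, Ts8, Ts11 and Ts15, 67.1%, 74.97%, 71.8% and 77.0% of the genes of the chromosome were above their diploid level, against 51.2%, 50.6%, 51.4% and 55.2% of the other genes. Between 15.1% and 19.4% exceeded log2(3/2). For each of the 4 chromosomes the exact two-sided permutation test of the 2 arrays of the line against the other 8 gave p = 0.022, the smallest that 45 splits can give. The competitive camera test gave p = 1.1e-06, 3.3e-12, 6.7e-09 and 1.7e-09 in the order of the lines, and p = 0.021, 0.0044, 0.029 and 0.027 with an estimated correlation. Among the 8 arrays of slide 1, the exact permutation p for Ts6, Ts8 and Ts11 was 0.036, the smallest that 28 splits can give. Slide 2 held Ts15 alone. On its arrays chromosome 15 was at 0.23 and 0.21, and the other autosomes lay between -0.05 and 0.04.

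**Figure D1:**
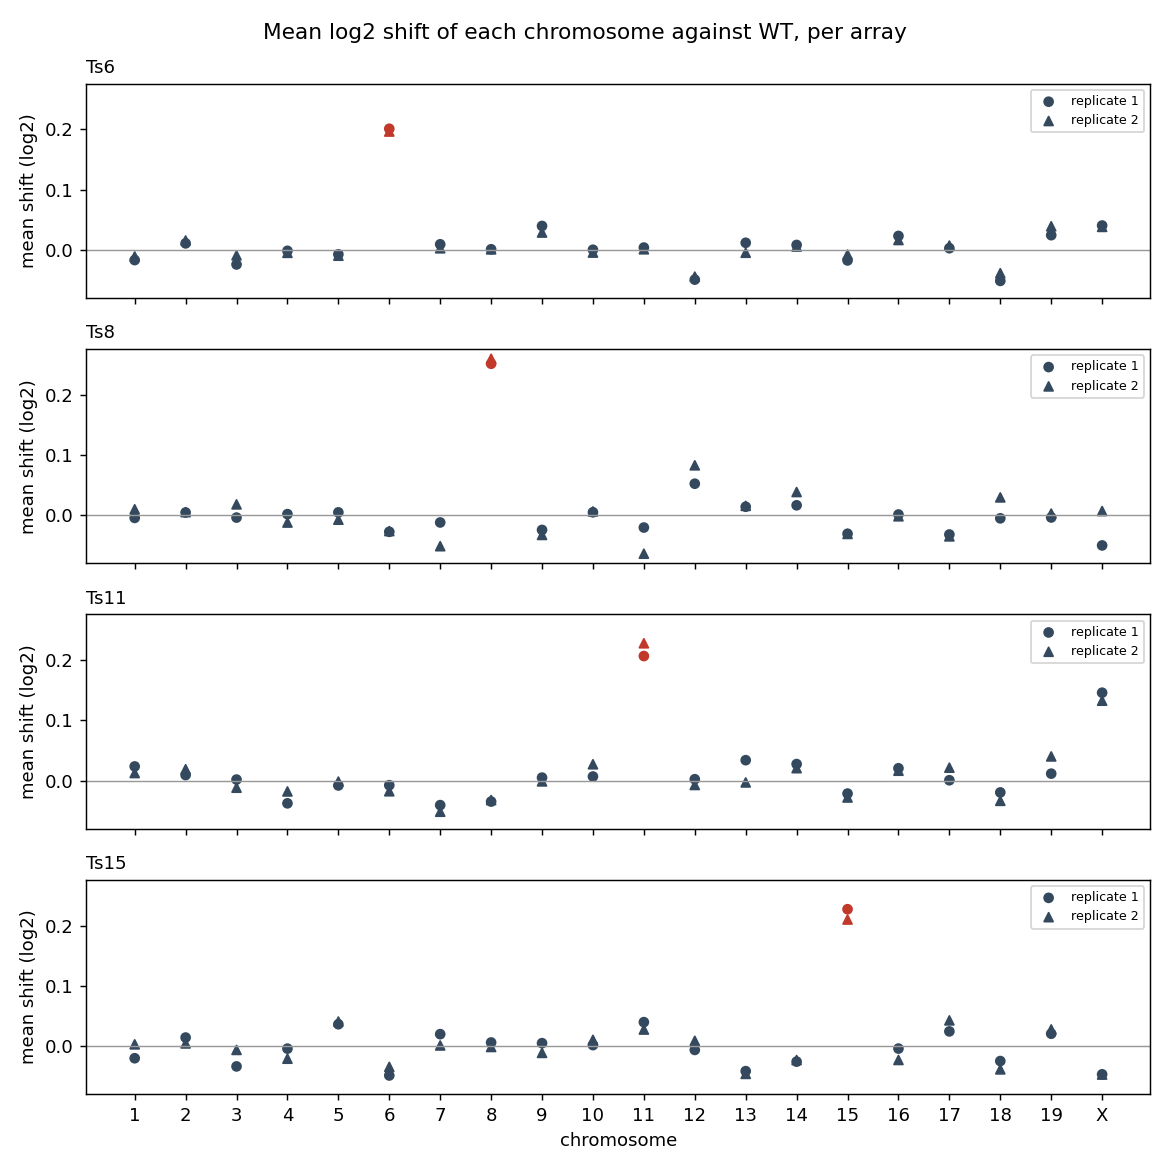
Mean log2 shift of each chromosome (1 to 19 and X, x axis) against diploid cells (y axis), in 1 panel per trisomic line; a circle marks replicate 1, a triangle replicate 2, and red the trisomic chromosome. The red symbols lie between 0.20 and 0.26, above the other autosomes of the same arrays.

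Genes of different expression level and RNA class on these chromosomes were compared next. The shift was smallest in the dimmest tertile of genes (0.14, 0.21, 0.17 and 0.18 in Ts6, Ts8, Ts11 and Ts15) and highest in the middle tertile (0.25, 0.31, 0.28 and 0.26). In the brightest tertile it was 0.21, 0.25, 0.21 and 0.20, with an SD of at most 0.01 between the 2 arrays of a line. The 240 lincRNAs of chromosome 6 shifted by 0.12 ± 0.02 (SD, n = 2) and the 178 of chromosome 15 by 0.09 ± 0.03, below the 0.21 ± 0.0007 and 0.24 ± 0.008 of the other genes of these chromosomes. LincRNAs of chromosomes 8 and 11, at 0.25 ± 0.04 and 0.20 ± 0.04, differed from the other genes (0.25 and 0.22) by less than that spread. LincRNAs and other genes were not matched for signal, so a difference between them cannot be told apart from one of signal. These differences between classes were set against the spread of 2 arrays, which is not the spread over genes, and not tested further.

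**Figure D2:**
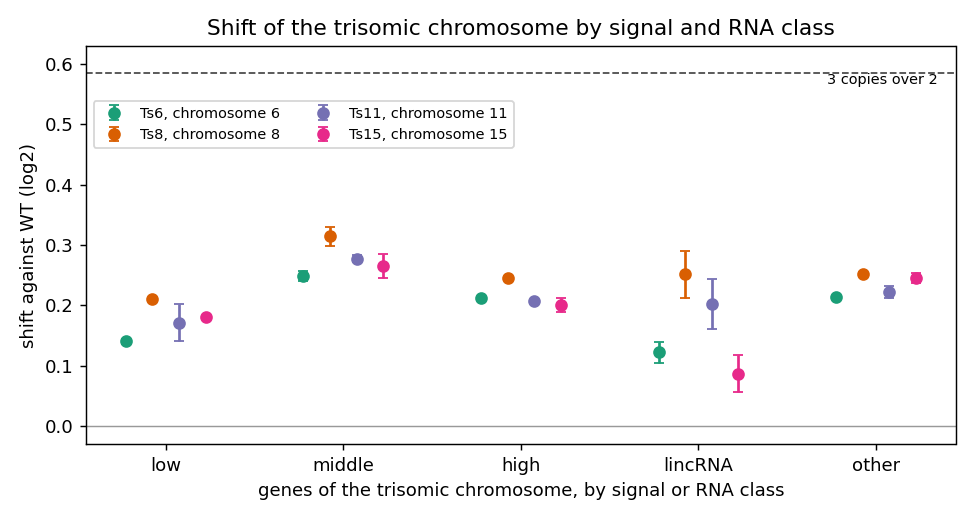
Mean log2 shift of the trisomic chromosome (y axis) in each of the 4 lines for genes of low, middle and high signal, lincRNAs and other genes (x axis), with the SD of 2 arrays as error bars and log2(3/2) as a dashed line. In the high class the values are 0.21, 0.25, 0.21 and 0.20, all far under the dashed line at 0.58.

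Signal of the Y chromosome, which the male WT cells carry, was read from Y-linked genes. Eif2s3y, a translation initiation factor gene on the Y chromosome (mm9, chromosome Y 364951 to 365010), was well above background in all 4 arrays of WT and Ts15 and in none of the 4 arrays of Ts6 and Ts11. It was at least 175-fold lower in Ts6 (limma adjusted p = 1.8e-06) and at least 128-fold lower in Ts11 (adjusted p = 1.3e-06). In Ts8 it fell by 3.82 ± 0.18 on the log2 scale (SE; adjusted p = 0.00056) and kept 7.09% of the WT level. Ddx3y, an RNA helicase gene (chromosome Y 598215 to 598274), was at least 63.3-fold lower in Ts6 and at least 46.3-fold lower in Ts11, and kept 5.74% of the WT level in Ts8. Uty, a histone demethylase gene, was at least 2.77-fold, 3.07-fold and 2.02-fold lower in Ts6, Ts8 and Ts11. In Ts15 the change of Eif2s3y was 0.04 ± 0.18 (adjusted p = 0.92). Eif2s3y was lower in Ts8 than in Ts15 (-3.86 on the log2 scale; limma adjusted p = 0.00044). As a list, the 7 Y-linked genes fell by 2.90 in Ts6 (camera adjusted p = 0.0019, and adjusted p = 0.18 with an estimated correlation). The list fell by 1.65 in Ts8 (adjusted p = 0.0016, and adjusted p = 0.27 with an estimated correlation). It fell by 2.77 in Ts11 (adjusted p = 0.0045, and adjusted p = 0.22 with an estimated correlation). In each of these lines 3 of the 7 genes fell. These means include signals at background, and with every array set at least at its lowest signal well above background they were -2.20, -1.38 and -1.74. In Ts15 the list mean was 0.18 (1 rose; adjusted p = 0.62). Adjusted over the list alone the 3 falls were the same, and 2 members rose in Ts11. The probes for Sry, Ube1y1 and Zfy2 stayed above background on all 10 arrays; the sign of Ube1y1 in Ts8 turned from 0.37 to -2.00 when all of its probes were averaged.

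**Figure D3:**
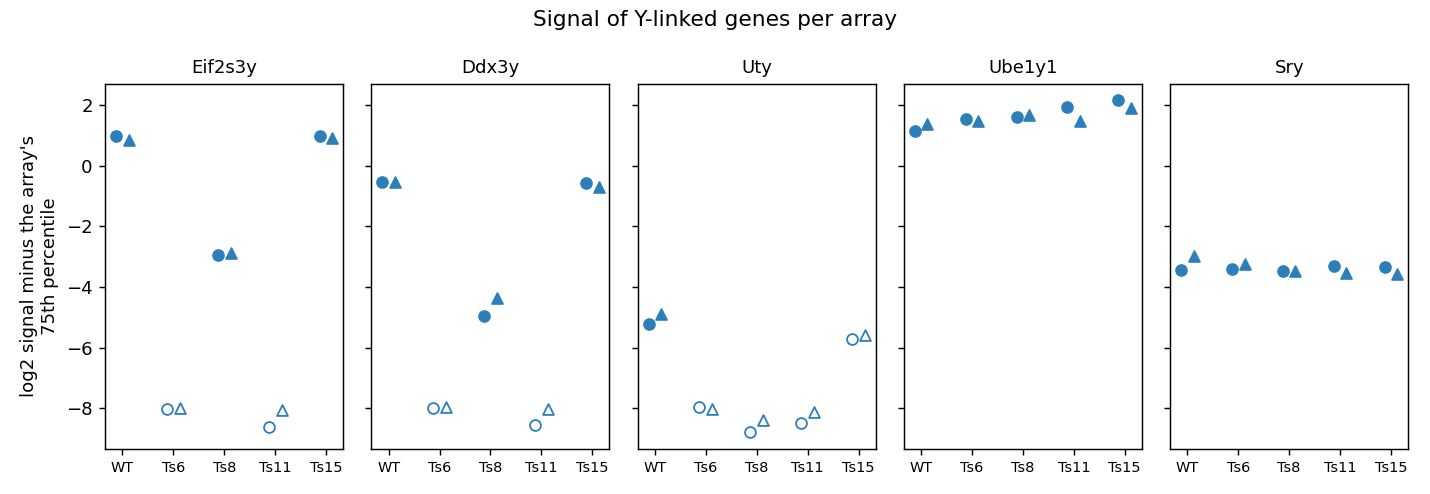
Normalised log2 signal (y axis) of 5 Y-linked genes per array, by group (x axis); circles are replicate 1, triangles replicate 2, and filled symbols mark genes well above background on both arrays of the group. Eif2s3y lies between 0.85 and 0.99 in WT and Ts15, near -2.9 in Ts8, and between -8.64 and -8.00 in Ts6 and Ts11.

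Ts6 cells were compared with diploid cells to find which genes change with an extra chromosome 6. Genes of the 2-cell-like state, a transient ES cell state that shares transcripts with the early embryo, fell together: 17 of 23 tested members fell and none rose (18 fell and 1 rose adjusted over the list alone). The mean change was -1.25 on the log2 scale (camera adjusted p = 6.3e-13, and adjusted p = 0.18 with an estimated correlation). Zscan4c, a zinc finger gene that marks this state (mm9, chromosome 7 11594425 to 11594484), fell by 1.95 ± 0.14 (SE, 2 arrays per group; adjusted p = 0.0006), and Zscan4e, Gm4340 and Zscan4f fell by 1.71, 1.63 and 1.56. Several members, such as the Zscan4 genes, belong to the same gene family, so the count is not one of independent changes. Whether their probes read separate transcripts was not tested, here or in the other lines. Imprinted genes fell by 0.46 on average, with 6 of 23 called and 9 adjusted over the list alone (adjusted p = 0.00047, and adjusted p = 0.18 with an estimated correlation). Among them were Grb10, a growth-restraining adaptor (-2.18), Cdkn1c, an inhibitor of cyclin-dependent kinases (-0.95), and the noncoding RNAs Meg3 (-0.95) and Mirg (-0.86). On chromosome 6 itself, Dppa3, a maternal factor that protects DNA methylation in the early embryo (mm9, chromosome 6 122580207 to 122580266), rose by 3.04 ± 0.35 (adjusted p = 0.0027). The protease inhibitor gene A2m rose by 2.60, the piRNA pathway gene Asz1 by 2.35, the mitochondrial carrier gene Slc25a18 by 1.79 and the taste receptor gene Tas2r103 by 1.77.

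Markers of primed epiblast, endoderm and neuroectoderm were lower in Ts6. Primed epiblast genes fell by 0.61 on average, with 4 of 18 called, among them Sall2 (-1.69), Pim2 (-1.42), Sox3 (-1.02) and Cdh2 (-0.99; list adjusted p = 0.0044, and adjusted p = 0.50 with an estimated correlation). Primitive and visceral endoderm genes fell by 0.38, with 3 of 25 called, the endocytic receptor gene Lrp2 (-1.37), Sox18 (-1.51) and Dab2 (-0.73; list adjusted p = 0.008, and adjusted p = 0.53 with an estimated correlation). Neuroectoderm genes fell by 0.37, with 4 of 19 called, the intermediate filament gene Nes (-1.20), Neurod1 (-1.02), Sox11 (-0.81) and Lhx2 (-0.80; list adjusted p = 0.019, and adjusted p = 0.18 with an estimated correlation). Wnt targets fell by 0.39, with Wnt8a (-2.01), Sp5 (-1.22) and Axin2 (-0.93) among 5 of 14 that fell while the homeobox gene Cdx1 rose by 1.98 (adjusted p = 0.028, and adjusted p = 0.51 with an estimated correlation). Adjusted over the list alone, 6 primed, 7 endoderm, 4 neuroectoderm and 5 Wnt genes fell, and 1 primed and 1 Wnt gene rose. Cell adhesion and matrix genes fell by 0.31, with Cdh2 and the tight junction gene Cldn3 (-0.95) among 4 of 29 called and 8 adjusted over the list alone (adjusted p = 0.0044, and adjusted p = 0.18 with an estimated correlation). Markers of the fibroblast feeder cells that the lines were grown on moved with them, at -0.33 with Col5a2 (-1.21, above background on 1 Ts6 array) called of 31 and none adjusted over the list alone (adjusted p = 0.0047, and adjusted p = 0.85 with an estimated correlation). Without Ts6 replicate 1 the feeder mean was -0.18 and its call ended (adjusted p = 0.14). The Wnt call ended without WT replicate 1 or Ts6 replicate 2 (adjusted p = 0.064 and 0.12).

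Some groups rose in Ts6. The unfolded protein and amino acid response was higher by 0.25 (adjusted p = 0.019, and adjusted p = 0.72 with an estimated correlation). Of 26 tested members, Chac1, an enzyme that degrades glutathione (1.06), and Herpud1, a factor of the degradation of misfolded proteins (0.78), were called. Germline genes were higher by 0.24 (adjusted p = 0.04, and adjusted p = 0.85 with an estimated correlation). Of 20 tested members, the meiotic genes Brdt (1.49) and Sycp3 (0.72) were called. Glycolysis and hypoxia genes were higher by 0.20 (adjusted p = 0.024, and adjusted p = 0.89 with an estimated correlation). Of 25 tested members, Ero1a (0.82) was called. Adjusted over the list alone the counts were the same. The unfolded protein call ended without WT replicate 2 or Ts6 replicate 2 (adjusted p = 0.25 and 0.091), and the germline call without WT replicate 2 or Ts6 replicate 1 (adjusted p = 0.14 and 0.097). The glycolysis call ended without WT replicate 2 or Ts6 replicate 1 (adjusted p = 0.24 for both), and its mean was 0.08 without Ts6 replicate 1 and 0.31 without Ts6 replicate 2. Trophectoderm genes were not called as a list (adjusted p = 0.68), although 4 of 17 rose: Tpbpa, at least 3.76-fold, Esx1 (1.22), Hand1 (1.11) and Sct (0.61). Mesoderm and interferon lists were not called either (adjusted p = 0.35 and 0.078). Of mesoderm genes Cdx1 and Hand1 rose while Isl1 and Mesp1 were at least 1.38-fold and 1.5-fold lower. Of interferon genes the antiviral genes Irf7 (0.88) and Rsad2 (0.73) rose and the peptide transporter gene Tap1 fell by 0.84.

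Over all genes, 1247 rose and 1301 fell in Ts6 (limma, adjusted p under 0.05), with 563 and 711 changed at least 2-fold. Of the 1247, 208 lay on chromosome 6 (odds ratio 4.12, 95% interval 3.50 to 4.84, Fisher's exact p = 4.3e-53). This test, here and in the other lines, takes genes as independent, which they are not. Its interval and p do not measure the spread between arrays. Outside that chromosome the lipoxygenase gene Alox12b rose by 2.75. Ldc1, Nms, Ccdc183 and the X-inactivation RNA XIST rose by 4.06, 3.73, 2.98 and 2.87 ± 0.68, but each was above background on 1 WT array, so the sizes are uncertain. Ctxn3, the serum amyloid P gene Apcs, Rassf9, Gtsf1l and the junctophilin gene Jph4 fell by 2.80, 2.72, 2.71, 2.65 and 2.59. The receptor tyrosine kinase gene Ros1, Abca16 and Retnla were at least 10.4-fold, 8.53-fold and 8.51-fold higher than in WT, where no array was above background. Abca16 (-3.757 and -3.639) and Retnla (-3.761 and -3.642) had nearly the same signal in the 2 Ts6 arrays. Retnla also differed between the 2 Ts15 arrays (-4.707 and -8.337). Whether these signals are expression was not tested, so their sizes are uncertain. The probes of Ldc1, Nms, Ccdc183, Ros1 and Abca16 lay on the right side of the array, where 87.4% of the genes dim in WT and called higher in Ts6 lay, against 71.0% of all tested genes dim in WT and 49.9% of all tested genes. The count of 2548 calls fell to 817 with passage as a covariate and to 1665 with only the 4 arrays compared. It was 1488 and 1331 without WT replicate 1 or 2, and 796 and 1553 without Ts6 replicate 1 or 2. On slide 1 alone it was 2055. In every group the higher passage was replicate 2, in slide row 2. The passage covariate thus cannot be told apart from slide row, here or in the other comparisons, and its lower counts do not show a cause.

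Ts8 cells were compared with diploid cells in the same way. Germline genes were higher in Ts8, with 7 of 22 risen and 1 fallen (11 and 1 adjusted over the list alone) and a mean of 0.52 (camera adjusted p = 0.00015, and adjusted p = 0.60 with an estimated correlation). Genes of the piRNA pathway, which silences transposons in germ cells, were among them: Tdrkh rose by 1.68 ± 0.22 (SE, 2 arrays per group; adjusted p = 0.02) and Tdrd1 by 1.29, with Tex101 at 1.28 and the germ cell helicase gene Ddx4 at 0.73. Of the genes the naming rule allowed, the one with the highest rise outside chromosome 8 was Meiob, a meiotic recombination gene (mm9, chromosome 17 24976585 to 24976644), at 2.74 ± 0.34 (adjusted p = 0.018), followed by Ms4a15 (2.29), Ninj2 (2.03), the Wnt-enhancing R-spondin gene Rspo4 (1.95) and Tarm1 (1.94). On chromosome 8, Terb1, which tethers meiotic telomeres, rose by 2.26, Kctd19 by 1.91, Ldhd by 1.72, Tmed6 by 1.71 and the phosphatase gene Dusp26 by 1.69, and Fa2h was at least 4.005-fold higher. Gkn2, a gastrokine gene (mm9, chromosome 6 87329285 to 87329344), fell by 4.58 ± 0.61 (adjusted p = 0.02), the connexin gene Gjb5 by 2.79 and Rassf9 by 2.75. Ms4a15 was above background on 1 WT array, and Gjb5 and Rassf9 on 1 Ts8 array, so the sizes of these changes are uncertain. Nectin4 was at least 3.09-fold higher, and Mucl3 and Nlrp9b at least 3.39-fold and 2.97-fold lower.

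Lists of LIF, Wnt, trophectoderm, mesoderm, interferon and adhesion genes were lower in Ts8. Lists of primed epiblast, endoderm, neuroectoderm and ERK targets were not called there (adjusted p = 0.080, 0.24, 0.28 and 0.28). Targets of LIF and Stat3, the pathway that sustains ES cell self-renewal, fell by 0.39 on average (adjusted p = 0.00035, and adjusted p = 0.27 with an estimated correlation). Of 16 tested members, the transcription factor gene Tfcp2l1 (-0.65), the LIF co-receptor gene Il6st (-0.52) and the kinase gene Pim1 (-0.58) were among the genes called, and 6 were called when adjusted over the list alone. Wnt targets fell by 0.61 (adjusted p = 0.0015, and adjusted p = 0.27 with an estimated correlation). Of 14 tested members, Wnt8a (-2.31), the mesoderm regulator T (-1.45) and Sp5 (-1.04) were called, and 5 fell and 1 rose adjusted over the list alone. Trophectoderm genes fell by 0.48 (adjusted p = 0.00088, and adjusted p = 0.27 with an estimated correlation). Of 19 tested members, Cdx2 (-1.40) and Peg10 (-0.85) were called, and 7 fell and 2 rose adjusted over the list alone. Mesoderm genes fell by 0.49 (adjusted p = 0.018, and adjusted p = 0.60 with an estimated correlation). Of 19 tested members, Cdx2, T and the homeobox gene Evx1 (-0.995) were called, and 8 fell and 2 rose adjusted over the list alone. Interferon response genes fell by 0.28 (adjusted p = 0.0016, and adjusted p = 0.60 with an estimated correlation). Of 32 tested members, the immunoproteasome gene Psmb8 (-1.47) and Xaf1 (-0.64) were called, and 6 fell and 1 rose adjusted over the list alone. Cell adhesion and matrix genes fell by 0.29 (adjusted p = 0.00088, and adjusted p = 0.27 with an estimated correlation). Of 28 tested members, Cldn3 (-0.86) was called, and 3 when adjusted over the list alone. Feeder cell markers were lower, at -0.23 in the same cells, with none of 33 called at either adjustment (adjusted p = 0.0038, and adjusted p = 0.61 with an estimated correlation). Without Ts8 replicate 2 the interferon mean was -0.16 and the feeder mean -0.12, and the feeder call ended (adjusted p = 0.052). The mesoderm mean was -0.77 without Ts8 replicate 1 and -0.21 without Ts8 replicate 2, where its call ended (adjusted p = 0.052).

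Some metabolic and growth lists shifted in Ts8 with few single genes called. Glycolysis, oxidative phosphorylation, lysosome, Myc target, DNA replication and mitosis lists were not called (adjusted p = 0.087, 0.13, 0.28, 0.082, 0.92 and 0.24). Cholesterol synthesis genes were lower, at -0.47, 22 of 23 below WT and none called (adjusted p = 8.5e-05, and adjusted p = 0.60 with an estimated correlation). That mean was -0.26 without WT replicate 2 and also -0.26 without Ts8 replicate 2, and the WT arrays themselves lay at -0.22 and 0.22 over 25 cholesterol genes. Cytosolic ribosome genes were lower, at -0.16, with Rpl14 (-0.62) called of 50 (adjusted p = 0.00088, and adjusted p = 0.60 with an estimated correlation). Their mean was 0.01 after quantile normalization, a change of direction. Proteasome genes were lower, at -0.14, with none of 34 called (adjusted p = 0.0022, and adjusted p = 0.60 with an estimated correlation). The 2-cell-like genes were higher by 0.26, with the transcription factor gene Dux (1.08), which switches on this state, called of 23 (adjusted p = 0.0086, and adjusted p = 0.60 with an estimated correlation). Targets of p53 were higher by 0.26 with none of 26 called (adjusted p = 0.023, and adjusted p = 0.60 with an estimated correlation). The 2-cell-like call ended without Ts8 replicate 1 (mean 0.17, adjusted p = 0.12). The p53 call ended without WT replicate 2 (mean 0.14, adjusted p = 0.32) or Ts8 replicate 2 (mean 0.16, adjusted p = 0.14). Imprinted genes were not called as a list (adjusted p = 0.38), with Peg12 (-1.38), H19 (-0.85) and Peg10 fallen and Cdkn1c risen by 0.66. In all, 545 genes rose and 421 fell, 141 of the 545 on chromosome 8 (odds ratio 6.76, 95% interval 5.50 to 8.28, Fisher's exact p = 4.9e-58). The balance depended on scaling. Here 56.4% of the calls were higher, against 48.2% after quantile normalization and 47.3% after centring on genes outside the trisomic and sex chromosomes. The share was 54.0% with normexp background correction and 57.0% with the deposited log2 values. The count of 966 rests on the spread pooled over all 10 arrays: it was 1 with only the 4 arrays compared and 229 on slide 1 alone. With passage as a covariate, which keeps all 10 arrays but goes with slide row within every group, the count was 6. It was 353 and 93 without WT replicate 1 or 2, 1835 and 10 without Ts8 replicate 1 or 2, 176 without either Ts6 array and 229 without either Ts15 array.

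Ts11 cells were higher in the unfolded protein and amino acid response. This list joins genes that cells switch on when proteins misfold in the endoplasmic reticulum with genes of the amino acid response. Its parts were not tested apart. All 28 tested members were higher than in diploid cells, by 0.67 on average, and 5 were called (15 adjusted over the list alone; camera adjusted p = 1.2e-09, and adjusted p = 0.22 with an estimated correlation). Herpud1, which helps to degrade misfolded proteins (mm9, chromosome 8 96919117 to 96919176), rose by 1.81 ± 0.12 (SE, 2 arrays per group; adjusted p = 0.00072), Trib3 by 1.05, the chaperone gene Dnajb9 by 0.99 and Sel1l by 0.77. Germline genes were higher by 0.49 (adjusted p = 3.5e-05, and adjusted p = 0.36 with an estimated correlation). Of 22 tested members, Asz1 (1.72), Sycp1 (1.29), Tex101 (1.19) and Brdt (1.14) were called, and 11 when adjusted over the list alone. Outside chromosome 11, Dppa3 rose by 3.22 ± 0.35 (adjusted p = 0.0037), as did 4 genes of the X-linked lymphocyte-regulated cluster, Xlr3b (mm9, chromosome X 70448087 to 70448146) and Xlr3a by 3.17 each, Xlr4a by 2.97 and Xlr4d-ps by 2.92. On chromosome 11, B4galnt2 rose by 2.41, Prss38 by 2.37, the meiotic gene Hormad2 by 2.16, the steroid dehydrogenase gene Hsd17b1 by 2.14 and the sulfatase gene Arsg by 1.99. Dnajc5g and Akr1cl were at least 5.08-fold and 4.30-fold higher. Gkn2 fell by 4.60 ± 0.61 (adjusted p = 0.0071), Ccdc3 by 3.07, the synaptotagmin gene Syt13 by 2.64, Fam43b by 2.53 and the defensin gene Defa29 by 2.30. Fam43b and Defa29 were above background on 1 Ts11 array, so the sizes of their falls are uncertain.

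The 2-cell-like genes fell in Ts11 by 0.49 on average, with 12 of 22 fallen and 2 risen (13 and 2 adjusted over the list alone; adjusted p = 9.1e-06, and adjusted p = 0.34 with an estimated correlation). Zscan4c (-1.21), Gm4340 (-1.12) and Zscan4e (-1.02) fell while Pramel7, a gene of early embryos and ES cells, rose by 1.97. All 10 Wnt targets tested were lower, at -0.94 on average (adjusted p = 2.0e-05, and adjusted p = 0.22 with an estimated correlation). Wnt8a (-1.83), Cdx1 (-1.07) and the receptor gene Fzd7 (-0.64) were called, and 8 when adjusted over the list alone. Primed epiblast genes fell by 0.69, with the Nodal antagonist genes Lefty2 (-1.14) and Lefty1 (-1.06), Sall2 (-1.63) and Pim2 (-0.85) among 6 of 18 called, and 9 fallen and 1 risen adjusted over the list alone (adjusted p = 0.00058, and adjusted p = 0.34 with an estimated correlation). Endoderm genes fell by 0.45 (adjusted p = 0.00058, and adjusted p = 0.34 with an estimated correlation). Of 23 tested members, Sox18 (-1.43), Srgn (-0.99) and Lrp2 (-0.82) were called, and 5 fell and 1 rose adjusted over the list alone. Mesoderm genes were lower, at -0.35 (adjusted p = 0.032, and adjusted p = 0.50 with an estimated correlation). Of 16 tested members, Cdx1 was called, and 5 when adjusted over the list alone. LIF and Stat3 targets fell by 0.32 (adjusted p = 0.02, and adjusted p = 0.36 with an estimated correlation). Of 15 tested members, Gbx2 (-1.26), Junb (-0.85) and Pim1 (-0.63) were called, and 5 when adjusted over the list alone. Cell adhesion and matrix genes were lower, at -0.23, with Cldn3 (-1.35) the 1 call of 28 at either adjustment (adjusted p = 0.02, and adjusted p = 0.34 with an estimated correlation). Feeder cell markers had a mean of -0.15 there and were not called (adjusted p = 0.29). The 2-cell-like mean was -0.32 without Ts11 replicate 1. The mesoderm call ended without WT replicate 2 or Ts11 replicate 2 (adjusted p = 0.082 and 0.056), the LIF call without WT replicate 2 or Ts11 replicate 1 (adjusted p = 0.064 and 0.058), and the adhesion call without WT replicate 1 (adjusted p = 0.060).

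Cholesterol synthesis genes were lower in Ts11, at -0.52, 23 of 25 below WT, with the regulator Srebf2 (-0.95) called (adjusted p = 6.3e-05, and adjusted p = 0.57 with an estimated correlation). Cytosolic ribosome genes were lower, at -0.19, with Rps16 (-0.51) called of 47 and none adjusted over the list alone (adjusted p = 0.00026, and adjusted p = 0.57 with an estimated correlation). Lysosome genes were higher by 0.14 with none of 28 called (adjusted p = 0.032, and adjusted p = 0.64 with an estimated correlation). The cholesterol mean was -0.30 without WT replicate 2, and the ribosome mean -0.13 without Ts11 replicate 2. The lysosome mean was 0.09 without WT replicate 2 (adjusted p = 0.26), 0.23 without Ts11 replicate 1 and 0.05 without Ts11 replicate 2 (adjusted p = 0.65). Lists not called still held single changes. Among pluripotency genes (list adjusted p = 0.59) Dppa3, given above, rose most of the named members, Jam2 (0.96) and Tet2 (0.49) rose too, and Lin28a fell by 0.54. Cdkn1c (-0.81), Mirg (-0.84) and Phlda2 (-0.84) fell among imprinted genes (list adjusted p = 0.099). Sox11 (-0.87) and Gbx2 fell among neuroectoderm genes (list adjusted p = 0.56), and the tumour suppressor gene Rb1 rose by 0.81 (list adjusted p = 0.37). Over all genes, 1158 rose and 1137 fell, 268 of the 1158 on chromosome 11 (odds ratio 4.41, 95% interval 3.7997 to 5.1053, Fisher's exact p = 5.3e-71). The count of 2295 was 46 with passage as a covariate, 282 with only the 4 arrays compared, and 1472 on slide 1 alone, the same as without either Ts15 array. It was 1250 and 816 without WT replicate 1 or 2, 1078 and 938 without Ts11 replicate 1 or 2, and 1450 without either Ts6 array. With the deposited log2 values 64.9% of the calls were higher, against 50.5%.

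Ts15 cells, all on slide 2, were higher than diploid cells in markers of primitive and visceral endoderm, the extraembryonic lineages that form the yolk sac. Of 24 members 14 rose and none fell (16 and 1 adjusted over the list alone), with a mean of 0.80 (camera adjusted p = 6.5e-09, and adjusted p = 0.24 with an estimated correlation). The endoderm regulator Sox17 (mm9, chromosome 1 4481503 to 4481562) rose by 2.48 ± 0.26 (SE, 2 arrays per group; adjusted p = 0.0034), Srgn by 1.46, the transcription factor gene Gata4 by 1.38 and the basement membrane collagen gene Col4a2 by 0.88. Trophectoderm genes were higher by 0.44 (adjusted p = 0.00091, and adjusted p = 0.24 with an estimated correlation). Of 16 tested members, the secretin gene Sct (1.35), Hand1 (1.32) and Tfap2c (0.51) were called at either adjustment. Feeder cell markers moved the same way, by 0.20 (adjusted p = 0.0036, and adjusted p = 0.71 with an estimated correlation). Of 33 tested members, the matrix gene Sparc (0.55) and the smooth muscle actin gene Acta2 (0.66) were called. The feeder mean rested on 1 array: it was 0.36 without Ts15 replicate 1 and 0.05 without Ts15 replicate 2, where the call ended (adjusted p = 0.39). The unfolded protein and amino acid response was higher by 0.47 in 27 of 28 genes, with Chac1 (1.19), the stress factor gene Atf3 (1.08) and Herpud1 (0.97) called and 7 adjusted over the list alone (adjusted p = 3.6e-07, and adjusted p = 0.37 with an estimated correlation). Interferon response genes were higher by 0.26 (adjusted p = 0.001, and adjusted p = 0.71 with an estimated correlation). Of 33 tested members, the antiviral genes Rsad2 (0.93) and Ifit3 (0.88) were called, and 4 when adjusted over the list alone. This list call ended without Ts15 replicate 2 (adjusted p = 0.068). Germline genes were higher by 0.25, with Tex101 (1.36), Tdrkh (1.12) and Tdrd1 (0.52) among 4 of 22 that rose while Asz1 fell by 1.58 (6 and 1 adjusted over the list alone; adjusted p = 0.0035, and adjusted p = 0.71 with an estimated correlation).

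Broad metabolic lists moved little in Ts15. Lysosome genes were higher by 0.17 with Gabarapl2 (0.57) called of 32 (adjusted p = 0.0029, and adjusted p = 0.71 with an estimated correlation). Targets of p53 were higher by 0.19 with the autophagy gene Dram1 (1.15) called of 27 (adjusted p = 0.012, and adjusted p = 0.71 with an estimated correlation). Oxidative phosphorylation genes were higher by 0.10 with none of 41 called (adjusted p = 0.0064, and adjusted p = 0.71 with an estimated correlation), a direction that turned to -0.01 after quantile normalization. The p53 mean was 0.32 without WT replicate 1 and 0.07 without WT replicate 2. The oxidative phosphorylation mean was 0.06 without WT replicate 2, 0.05 without Ts15 replicate 1 and 0.15 without Ts15 replicate 2. Without WT replicate 2 the p53, lysosome and oxidative phosphorylation calls ended (adjusted p = 0.46, 0.074 and 0.26), as did the p53 call without Ts15 replicate 2 (adjusted p = 0.098) and the oxidative phosphorylation call without Ts15 replicate 1 (adjusted p = 0.14). Imprinted genes were not called as a list (adjusted p = 0.97), although Grb10 (-1.65), Ndn (-0.90) and Peg12 fell. Outside chromosome 15 the highest rises of genes the naming rule allowed were those of the protease gene Habp2 (2.74), Ly6g5c (2.64), Rfpl4b (2.55), Ldc1 (2.55) and Sox17. Ly6g5c, Rfpl4b and Ldc1 were above background on 1 WT array, so these sizes are uncertain. The sulfotransferase gene Chst3 fell by 2.15, Bend7 by 2.12, the matrix metalloprotease gene Mmp27 by 2.09 and the olfactory receptor genes Olfr574 and Olfr975 by 1.97 and 1.83. Spint3 was at least 2.90-fold higher and the growth factor gene Fgf6 at least 3.82-fold lower. On chromosome 15, Lypd2 rose by 1.94, the cadherin gene Cdh6 by 1.93, Efcab6 by 1.79, Adm2 by 1.67 and the galectin gene Lgals2 by 1.63, and Slc22a22 was at least 3.32-fold higher. In all, 736 genes rose and 1368 fell, of which 62 and 343 were lincRNAs, and 112 of the 736 lay on chromosome 15 (odds ratio 4.78, 95% interval 3.84 to 5.92, Fisher's exact p = 1.5e-35). Of the genes that fell, 35.0% lay on the right side of the array, against 49.9% of tested genes. The count of 2104 was 438 with passage as a covariate, 630 with only the 4 arrays compared, 1314 and 798 without WT replicate 1 or 2, and 825 and 763 without Ts15 replicate 1 or 2. The balance depended on scaling and background correction: 35.0% of the calls were higher here and 45.7% after quantile normalization. The share was 49.1% with normexp background correction and 51.3% with the deposited log2 values.

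**Figure D4:**
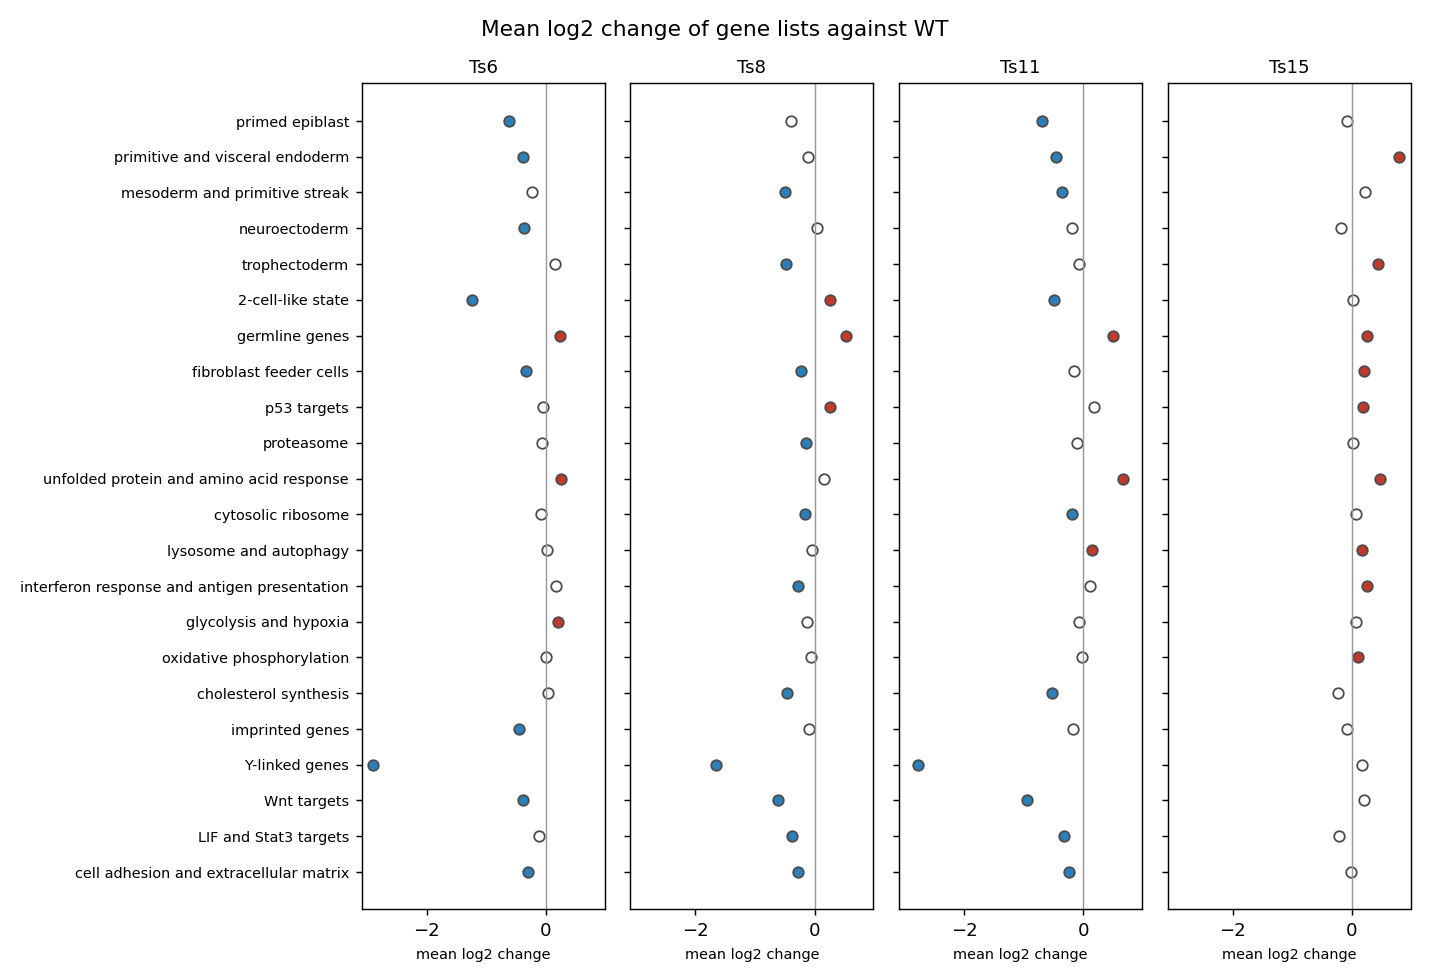
Mean log2 change against diploid cells (x axis) of 22 gene lists (y axis) in each trisomic line; filled red and blue symbols mark lists called higher or lower with the preset correlation, and open symbols lists not called. The 2-cell-like list lies at -1.25 in Ts6 and 0.26 in Ts8, and the endoderm list at 0.80 in Ts15 and -0.38 in Ts6.

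The mean of the 4 lines was also compared with diploid cells. Apart from Ts6 replicate 2, the arrays of the lines were at lower passages than WT, so this comparison can include a difference of passage. The unfolded protein and amino acid response was higher in all 20 members outside the 4 chromosomes, by 0.39 on average, with Chac1 (0.66) called and 6 adjusted over the list alone (camera adjusted p = 1.6e-05, and adjusted p = 0.41 with an estimated correlation). Germline genes were higher by 0.42 in 16 of 17 members, with Tex101 (1.01), Tdrkh (0.98), Tdrd1 (0.64) and Sycp3 (0.61) called and 7 adjusted over the list alone (adjusted p = 1.6e-05, and adjusted p = 0.41 with an estimated correlation). The 2-cell-like genes were lower, at -0.37, with Zscan4c (-0.78), Zscan4e (-0.66), Gm4340 (-0.60) and Gm8300 (-0.55) among 6 of 22 called, and 13 fallen and 1 risen adjusted over the list alone (adjusted p = 7.2e-05, and adjusted p = 0.41 with an estimated correlation). This mean joins falls in Ts6 and Ts11 with a rise in Ts8. Also lower were primed epiblast genes (-0.45; adjusted p = 0.0098), LIF and Stat3 targets (-0.27; adjusted p = 0.016), cell adhesion and matrix genes (-0.21; adjusted p = 0.017), imprinted genes (-0.21; adjusted p = 0.026) and Y-linked genes (-1.79; adjusted p = 0.008), each with adjusted p = 0.41 with an estimated correlation. Of their members, Sall2 (-1.18) and Pim2 (-0.71), Cldn3 (-0.74), Peg12 (-0.83) and Ndn (-0.52), and Eif2s3y (-5.49) fell, while no LIF target was called. Cholesterol synthesis (-0.29; adjusted p = 0.015) and cytosolic ribosome genes (-0.10; adjusted p = 0.032) were lower too, each with adjusted p = 0.73 with an estimated correlation. Wnt targets were lower, at -0.42 (adjusted p = 0.039, and adjusted p = 0.42 with an estimated correlation). Among them Wnt8a (-1.31) fell and Cdx1 (0.82) rose. Adjusted over the list alone, 6 primed, 4 LIF, 2 adhesion, 5 imprinted, 3 Y-linked and 5 Wnt genes fell, and 1 primed, 2 Y-linked and 1 Wnt gene rose. A called mean did not require a call in each line, and of these lists the germline list alone was called in all 4. The unfolded protein list was not called in Ts8 (0.16; adjusted p = 0.28) nor the 2-cell-like list in Ts15 (0.02; adjusted p = 0.82). In Ts15 the primed (-0.08), LIF (-0.21), adhesion (-0.01), imprinted (-0.09), Y-linked (0.18), cholesterol (-0.23), ribosome (0.06) and Wnt (0.21) lists were not called (adjusted p = 0.94, 0.16, 0.82, 0.97, 0.62, 0.16, 0.12 and 0.32). Primed and imprinted genes were not called in Ts8 (adjusted p = 0.080 and 0.38), imprinted genes in Ts11 (adjusted p = 0.099), and LIF, cholesterol and ribosome genes in Ts6 (adjusted p = 0.60, 0.67 and 0.28). The cholesterol mean was -0.50 without WT replicate 1 and -0.07 without WT replicate 2, where the call ended (adjusted p = 0.89). The ribosome mean was -0.05 without WT replicate 1 (adjusted p = 0.50), and its call also ended without Ts11 replicate 2 or Ts15 replicate 2 (adjusted p = 0.079 and 0.086). Without WT replicate 1 the primed, imprinted, adhesion and Wnt calls ended (adjusted p = 0.090, 0.18, 0.074 and 0.13), and without WT replicate 2 the LIF call (adjusted p = 0.066). The Wnt call ended too without Ts11 replicate 1, Ts11 replicate 2 or Ts15 replicate 2 (adjusted p = 0.052, 0.061 and 0.061). Of single genes outside the 4 chromosomes that the naming rule allowed, Ldc1 (2.55), Meiob (2.42 ± 0.27; adjusted p = 0.01), Ly6g5c (2.29), Ms4a15 (2.23), Adtrp (1.97), Tarm1 (1.73), the metal transporter gene Slc11a1 (1.58) and the noncoding RNA Platr26 (1.51) rose most. Ddx3y (-4.85), the Notch-pathway gene Hes3 (-2.14), the endocrine progenitor gene Neurog3 (-2.00), Ccdc3 (-1.96), Rassf9 (-1.87), Ctxn3 (-1.83) and Chst3 (-1.73) fell most, while Eif2s3y, whose level in Ts15 was not below WT, fell further. Ldc1, Ly6g5c, Ms4a15 and Adtrp were above background on 1 WT array, and Hes3 on 1 of the 8 arrays of the lines, so the sizes of these changes are uncertain. Eif2s3y and Ddx3y were at background in Ts6 and Ts11, and with arrays set at least at the lowest signal well above background they were at -4.56 and -3.93, Uty at -1.17 and the Y-linked list at -1.29. In all, 531 genes rose and 546 fell. That count of 1077 was 2 with passage as a covariate, 455 and 31 without WT replicate 1 or 2, 379 and 590 without Ts6 replicate 1 or 2, and 429 and 625 without Ts15 replicate 1 or 2. The 3 lines of slide 1 gave 1003.

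Core pluripotency genes stayed near their diploid level in every line. Pou5f1, Sox2, Nanog, Zfp42 and Klf4 differed from WT by -0.29 to 0.22 and none was called in any line. Nanog, on chromosome 6, was at 5.01 and 4.98 in the Ts6 arrays, below the 5.29 and 5.26 of WT. Zfp42, on chromosome 8, was at 4.35 and 4.21 in Ts8, above the 4.16 and 4.19 of WT. Changes of this size were seldom called in the simulated data, so a missing call does not show that a gene was unchanged. The tumour suppressor Trp53 differed by -0.08 to 0.17, and neither its target Cdkn1a (0.28 to 0.89) nor Myc was called. Myc, on chromosome 15, came nearest in Ts15, at 0.72 ± 0.18 (SE, 2 arrays per group; limma adjusted p = 0.054). The lists of naive pluripotency, heat shock, DNA replication, mitosis, ERK targets, Myc targets and tumour suppressors were called in no line, with means from -0.14 to 0.13 and a lowest adjusted p of 0.063, that of Myc targets in Ts11. Over the 4 lines and their mean, 59 list shifts were called by camera with the preset correlation and 0 with an estimated correlation, which gave an unadjusted p under 0.05 in 18. The test fry, which does not compare a list with other genes, called 35. Leaving out 1 array in turn ended 25 of the 59 calls at least once and moved the mean of 17 lists by more than 1.5 times. The mean, the median and the test differed in sign in no called list of these comparisons.

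Single genes called in the same direction in several lines were counted among 22138 genes outside the 4 trisomic chromosomes. In all 4 lines 31 genes rose and 21 fell, and in at least 3 lines 129 rose and 132 fell. All 4 lines were compared with the same 2 WT arrays, which could not be divided between them, so these counts include whatever sharing those arrays produce. The higher passages of WT can add to this sharing. The changes of the 2 lines of a pair correlated across genes (genes are not independent replicates) with r from 0.26 to 0.55, against 0.50 in simulated unchanged lines that shared the WT arrays. Changes of a line of its own lower r but not the covariance, which was 0.050 to 0.144 in the 6 pairs, above the simulated 0.025 in each. Meiob, the phagosomal transporter gene Slc11a1, the oocyte chromatin gene Npm2 and Ctcfl, a germline relative of the insulator protein CTCF, were among the 31, and Chst3 and the Hedgehog receptor gene Ptch1 among the 21. Apart from Meiob, Slc11a1 and Chst3 these were chosen after their values were seen. With a fold of at least 2 as well, 89 of the 261 genes remained called in at least 3 lines.

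Differences between lines were tested in all 6 pairs. Ts15 stood furthest apart, with 5147, 4805 and 4269 genes called against Ts6, Ts8 and Ts11, while Ts6 and Ts8 differed in 3858, Ts8 and Ts11 in 2193 and Ts6 and Ts11 in 2067. Ts15 is also the line on the other slide. The Xlr genes separated Ts11 from Ts6 and Ts8: Xlr3a was lower in Ts6 (-3.20 ± 0.17, log2, SE, 2 arrays per group; limma adjusted p = 0.0004) and in Ts8 (-3.47 ± 0.17; adjusted p = 0.00011) than in Ts11, and Xlr3b lower in Ts6 than in Ts11 (-3.04). Against WT the Xlr genes also rose in Ts15, Xlr3b by 1.08, Xlr4a by 0.99, Xlr3a by 0.91 and Xlr4d-ps by 0.82, values looked at after those of Ts11 were seen. Pramel6 was lower in Ts8 than in Ts11 (-3.84) and 3.30 higher in Ts11 than in Ts15, and Magea1 was 3.04 higher in Ts11 than in Ts15. Nms was higher in Ts6 than in Ts8, Ts11 and Ts15, by 3.11 ± 0.16, 3.42 ± 0.16 and 3.54 ± 0.16 (adjusted p = 0.00016, 0.0004 and 0.00016), on a probe on the right side of the array. Nms was above background on 1 Ts11 and 1 Ts15 array and Pramel6 on 1 Ts8 array, so these sizes are uncertain. Cdx1 was 3.05 higher in Ts6 than in Ts11. The calcium-binding gene S100g (-3.49) and the thrombomodulin gene Thbd (-3.46) were lower in Ts6 than in Ts15, Apcs (-3.13) was lower in Ts6 than in Ts8, and the X-inactivation antisense RNA TSIX was 2.30 higher in Ts8 than in Ts15. The adenosine receptor gene Adora1 (-3.31) and the water channel gene Aqp8 (-3.26) were lower in Ts11 than in Ts15. The unfolded protein and amino acid response list was lower in Ts8 than in Ts11, at -0.47, in 26 of 26 genes (camera adjusted p = 1.1e-07, and adjusted p = 0.33 with an estimated correlation). It was also lower in Ts6 than in Ts11, at -0.38 (adjusted p = 0.00092, and adjusted p = 0.75 with an estimated correlation). In the order Ts6 and Ts8, Ts6 and Ts11, Ts6 and Ts15, Ts8 and Ts11, Ts8 and Ts15, and Ts11 and Ts15, camera called 9, 5, 14, 5, 19 and 14 lists, of which an estimated correlation kept none. Over the 6 pairs the count of 22339 calls was 11373 and 13713 without Ts6 replicate 1 or 2, and 12483 and 11224 without Ts15 replicate 1 or 2.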

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

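The tests of differences between lines were fixed in advance for all pairs and lists, but those given in this part were picked by their results. Each gene list here was called in opposite directions in a pair of lines against WT, and the difference between those lines was itself called by camera, a call lost in each case with an estimated correlation. Opposite calls against the same WT arrays make a call between the lines likely, so that call is no separate support. The 2-cell-like list was lower in Ts6 than in Ts8, with a log2 difference of -1.505 (adjusted p = 4.2e-13, and adjusted p = 0.35 with an estimated correlation). In Ts8 it was higher than in Ts11 by 0.73 (adjusted p = 0.33 with an estimated correlation). The endoderm list differed by -1.16 between Ts6 and Ts15 (adjusted p = 0.14 with an estimated correlation) and by -1.25 between Ts11 and Ts15 (adjusted p = 0.092 with an estimated correlation). The trophectoderm list differed by -0.88 between Ts8 and Ts15 (adjusted p = 0.13 with an estimated correlation). The interferon list differed by -0.53 between the same lines (adjusted p = 0.38 with an estimated correlation). Feeder cell markers differed by -0.53 between Ts6 and Ts15 (adjusted p = 0.46 with an estimated correlation) and by -0.43 between Ts8 and Ts15 (adjusted p = 0.39 with an estimated correlation). The 6 differences that involve Ts15 cannot be told apart from a difference between the slides. Those within slide 1 cannot be told apart from a difference between slide columns.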

How the results depend on the processing

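The tests on slide 1 alone, the crossed replicate block and the correction for position on the array were chosen after the data were seen; the others were planned. The dosage shifts of chromosomes 6, 8, 11 and 15 kept direction and call under every alternative that left no array out. Counts of genes called, by contrast, moved by more than 1.5 times with many settings; the cause was not tested except where fewer genes or arrays enter by construction. With passage as a covariate, which goes with slide row within every group, they were 817 (Ts6), 6 (Ts8), 46 (Ts11), 438 (Ts15) and 2 (mean of the lines). With only the arrays compared they were 1665, 1, 282 and 630 in the 4 lines, and with at least a 2-fold change, a stricter threshold, 1274, 374, 850, 825 and 267. Without a filter on background they were 166 in Ts8, 1343 in Ts11, 1302 in Ts15 and 426 for the mean, and the expression-level value was 0.23. For Ts8, genes well above background on all arrays gave 1728, an intensity trend 2141, a robust trend 2098 and array weights 337; for the mean a trend gave 1698 and a robust trend 1653. Replicate number as a block (the replicate block) gave 2609, 660, 2273, 2170 and 982, within 1.5 times of the main counts; for Ts11, where the same-number correlation with WT was under -0.1, the crossed block gave 2680. Slide could not be fitted as a block for Ts15, which lies alone on slide 2. Slide 1 alone gave 2055 (Ts6), 229 (Ts8) and 1472 (Ts11), and the position correction 2648, 1009, 2291, 2070 and 1122. Camera with an estimated correlation left 0 of 59 list calls and fry called 35. The ribosome list in Ts8 turned to 0.010 and the oxidative phosphorylation list in Ts15 to -0.010 under quantile normalization, and Ube1y1 turned to -2.00 in Ts8 and -1.47 for the mean when probes were averaged; the cause was not tested. These 2 list calls ended, as did those of the germline genes in Ts6, the ribosome in Ts11 and for the mean, and the p53 targets and the lysosome and autophagy genes in Ts15. Of 334 named genes 53 lost their call on slide 1 alone, and of 415 named genes 30 lost it with the replicate block and 3 to 12 with each of the other 6 alternatives that kept all arrays. With at least a 2-fold change, 89 genes were called in the same direction in at least 3 lines. Leaving out an array gave 796 to 2435 genes in Ts6, 10 to 1835 in Ts8, 816 to 2450 in Ts11, 763 to 1980 in Ts15, 31 to 1300 for the mean, 11224 to 22211 over the pairs and 56 to 61 lists; a lone array of a group was assumed to vary like the other groups. The shifts were then 0.19 to 0.20 (chromosome 6), 0.25 to 0.26 (8), 0.21 to 0.23 (11) and 0.21 to 0.23 (15), with a permutation p up to 0.11 where a line kept 1 array, the smallest that 9 splits can give. Of 4150 repeats of named genes without an array, 3379 kept their side of the threshold, 731 lost the call and 40 gained it, with no direction turned. The 2 arrays per group, and the 71.4% to 80.2% of spots well above background, limit what could be detected.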

Other observations

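Genes with large changes often recurred in only some lines; these genes were named for at least 1 line by the rule, and their levels in the other lines were looked at after their values were seen. Dppa3, on chromosome 6, rose in Ts6 (3.04 ± 0.35, SE, 2 arrays per group) and in Ts11 (3.22 ± 0.35), where it is not on the trisomic chromosome, and was at 1.04 in Ts8 and 0.92 in Ts15 without a call (limma adjusted p = 0.13 and 0.16). Asz1, also on chromosome 6, rose in Ts6 (2.35) and Ts11 (1.72) and fell by 1.58 in Ts15. Gkn2 fell in Ts6 (-4.04), Ts8 (-4.58) and Ts11 (-4.60) and was at -0.97 in Ts15 (adjusted p = 0.37). Grb10 fell by 2.18 in Ts6 and 1.65 in Ts15. Meiob, on chromosome 17, rose in all 4 lines, by 2.48, 2.74, 2.15 and 2.30 in Ts6, Ts8, Ts11 and Ts15, and Herpud1, on chromosome 8, rose in all 4 too, by 0.78, 0.91, 1.81 and 0.97.

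LincRNAs were called in every line: 133 rose and 155 fell in Ts6, 112 rose and 24 fell in Ts8, 141 rose and 131 fell in Ts11, and 62 rose and 343 fell in Ts15. Some genes called between a line and WT were well above background on both arrays of 1 of these groups and on no array of the other. Of these, 108 were found in Ts6 alone and 218 in WT alone, 24 and 11 for Ts8, 23 and 59 for Ts11, and 11 and 296 for Ts15. Set against the lowest signal called well above background, 106 and 113 of the genes in Ts6 alone and WT alone differed at least 2-fold, 17 and 7 for Ts8, 19 and 20 for Ts11, and 8 and 43 for Ts15. The rest lay near the threshold, and 87.0% of the 108 genes had their probe on the right side of the array. Outside the trisomic chromosomes, Ts6 and Ts11 shared 250 genes that rose and 445 that fell, while 19 genes were called in opposite directions. Both lines were set against the same WT arrays, and their changes correlated across genes with r = 0.55, against 0.50 in simulated unchanged lines that shared those arrays, and had a covariance of 0.144 against 0.025.

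All tests of explanations in this part were chosen after the results were seen. Y-linked genes fell in Ts6, Ts8 and Ts11. Cells with 2 active X chromosomes are argued against for Ts6 and Ts8, where the highest mean shift of X-linked genes was 0.040, against 0.20 for the lowest mean shift of a trisomic chromosome. For Ts11 they stay open, since the highest mean shift was 0.15, although the median over genes was 0.06. XIST, which silences an X chromosome, rose by 2.87 in Ts6 from a level above background on 1 WT array, and an X chromosome silenced or lost was not tested. A candidate explanation for the rest of Y signal in Ts8 is a minority of cells that kept the Y chromosome: Ddx3y and Eif2s3y, each in 1 probe, fell by amounts that differed by -0.30, less than 2 times the SD of 0.37 between the 2 arrays. Feeder cells as its source were not supported by their markers: the mean in Ts8 was 0.032 above that of Ts6 and Ts11 together, and against WT it was -0.10 and -0.31 in the 2 arrays of Ts8, -0.005 and -0.28 in those of Ts11, and -0.48 and -0.19 in those of Ts6. Of dimmer markers, Pdgfrb, Cxcl12 and Col5a2 were at -0.87, -0.56 and -0.16 in Ts8 and Mmp2 at 0.70, none of them called. Feeder cells stay open all the same, since markers went both ways, all 34 tested were well above background in WT, 2 of 35 are in another list, and a small share would be hidden under levels such as Vim at 4.81 in Ts8 and 5.05 in WT. Whether Ts6, Ts8 and Ts11 ever carried a Y chromosome was not tested.

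The trisomic chromosomes rose by less than log2(3/2). Background that compresses dim probes does not account for all of it, since the highest array shift of the brightest tertile was 0.25, against 0.58. A flat response of the arrays as the whole cause is argued against by the highest of the 8 shifts, 0.26, under the lowest product of log2(3/2) and spike-in slope, 0.39. A lower shift at the higher passage, as after loss of the extra chromosome, was not seen in all lines: 2 of 4 had the higher shift there. The higher passage was also in the same slide row in every line, so passage and slide row cannot be told apart. A stable mixture of trisomic and diploid cells, and lower output per gene copy, were not tested and stay open.

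Ts6 had more genes called higher that were dim in WT (119) than the other lines, and Ts15 more genes called lower (1368) than higher (736). The Ts15 counts were 822 and 866 with the series table, and 776 and 750 with normexp background correction, so the excess of falls depended on the processing. Position on the array may account for part of the Ts6 excess and of the Ts15 falls. Of the Ts6 genes dim in WT and called higher, 87.4% (95% exact interval 80.1% to 92.8%; Fisher's exact p = 6.3e-08) had their probe on the right side of the array, against 71.0% of the 262 tested genes dim in WT, a class that includes them. For Ts6 genes well above background in both groups the share was 53.03% against 49.7% (Fisher's exact p = 0.024), which leaves a part of position undecided because the interval of 50.0% to 56.0% is too wide. Of the genes that fell in Ts15, 35.0% lay on the right side (95% exact interval 32.5% to 37.6%, Fisher's exact p = 8.9e-30). These exact tests take genes as independent, which they are not. The position correction removes shifts in the median signal of parts of the array. Such shifts as the whole cause are argued against in both lines, but position itself cannot be decided by it. With the position correction 120 dim genes were called higher in Ts6, against 27 in the highest other line, and 64.5% of the calls in Ts15 were lower (95% exact interval 62.4% to 66.6%). The correction left 87.5% of the dim Ts6 genes and 40.6% of the falls in Ts15 on the right side, so position effects that it did not remove stay open. In Ts15, alone on slide 2, slide and trisomy cannot be told apart, and no biological explanation for the position was tested.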
